A study of Homo sapiens with 24 samples.

How the data were processed

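The samples were K562 cells, an established human chronic myelogenous leukaemia line, carrying a CRISPR interference system in which doxycycline (50 ng/ml) turns on a repressor that a guide RNA directs to a promoter. The guide sgDDX3 is aimed at DDX3X, an X-linked gene for an RNA helicase that works in translation initiation, and sgGal4 is the control guide. Cells were taken at day 0, day 3 and day 14, and at each day 2 kinds of library were made: ribosome footprints and cytosolic RNA. For footprints, per the labels' protocols, lysates made with cycloheximide were digested with RNase I and ribosomes were collected on size-exclusion columns. For RNA, the Triton lysate was depleted of ribosomal RNA and made into directional libraries, so the RNA values are of the cytosol. Each of the 12 groups (guide, day and assay) held 2 libraries, 24 libraries in all. The labels give doxycycline for the day 0 samples as well, and do not state whether those cells had received it. The labels do not state that the replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

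The authors deposited whole-number read counts per gene, one table for each assay, with no normalization. Per the submitters' processing notes, cutadapt 3.4, Bowtie2 2.4.1, STAR 2.7.5a and DESeq2 were used with the genome build GRCh38, and the notes list the names with no order or role. The counting tool, the gene annotation, the strand setting and the treatment of reads that align to several places are not given in the sources used here. Values of overlapping genes, antisense genes, histone genes, pseudogenes and multi-copy small RNAs are therefore uncertain, since their reads can be shared. Each table had 58037 genes. The 45 copies of genes of the pseudoautosomal region that were listed on the Y chromosome repeated their X copies (126911 against 127237 RNA-seq counts, and 37711 against 38069 footprint counts), and were left out, so that 57992 genes were used. A symbol was found for 41445 of them (71.5%), which held at least 98.4% of the RNA-seq counts and 95.5% of the footprint counts of each library. Coordinates are those of the RefSeq table of GRCh38 given for this work. No genome sequence was used here, so GC content and untranslated regions were not analysed.

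Depth ranged from 1.03e+07 to 4.33e+07 counts per RNA-seq library (median 1.45e+07) and from 6.22e+06 to 1.52e+07 per footprint library (median 9.48e+06). A count of 0 therefore allows up to 3 counts, which is 0.207 CPM in the median RNA-seq library and 0.317 in the median footprint library. Intervals and limits of this kind cover counting error only, since reads without molecular identifiers are not independent molecules. The common biological coefficient of variation was 6.13% in RNA-seq, 9.99% in footprints and 7.08% in the joint model.

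The tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Counts of each assay were scaled by the trimmed mean of M values within the assay. Genes were kept by the filter filterByExpr with a minimum count of 10, which left 18287 genes in RNA-seq, 19780 in footprints and 14853 in both. Differences between the guides at each day, the change of that difference between days, and the change with time in sgGal4 were tested with the quasi-likelihood F-test of edgeR, with all 12 libraries of an assay in the fit, because 2 libraries are too few for a spread of their own. Translational efficiency, the footprints of a gene relative to its RNA, was tested as the interaction of guide and assay in a model of all 24 libraries. For non-coding genes this value need not measure translation. Adjusted p-values are Benjamini-Hochberg values and a gene passed at 0.05. Log2 differences are sgDDX3 over sgGal4 with their standard error (SE), and CPM (the counts of a gene per 1e+06 of its library) are given as mean ± SD with n = 2. In comparisons of the guides, genes that rose or fell were higher or lower than with sgGal4 at the same day, which is not a change over time. For single genes CPM are scaled by the same factors. A ratio of footprints to RNA is that of the mean CPM of the 2 assays and has no SD, because replicate numbers are not known to pair their libraries. The exceptions are of the total count: DDX3X, the values of TMTC2, LINC02955 and AGTR2, and those of MIR17HG where all 3 days are given.

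The design, the tests, the gene lists, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined. The rule named DDX3X; the 10 highest and 10 lowest genes by log2 difference among those that passed (5 and 5 at day 0 and for time in sgGal4) with a symbol, a mean of at least 10 CPM and groups that did not overlap (for translational efficiency in ratios matched by replicate number, a matching that is arbitrary); and up to 4 members of each list with the smallest p. Y-linked genes and the X-inactivation transcript were left out of it. Genes outside the rule are said to be so. There were 36 lists. Some covered translation: large and small ribosomal subunit proteins, other mRNAs with a 5′ terminal oligopyrimidine (TOP) motif, initiation factors, mRNAs named as DDX3X dependent in earlier work, RNA helicases, mRNA export, stress granule proteins, tRNA synthetases, ribosome biogenesis and mitochondrial ribosomal proteins. Others covered stress and metabolism: the integrated stress response, endoplasmic reticulum (ER) chaperones, heat shock, nuclear and mitochondrial genes of oxidative phosphorylation, cholesterol synthesis, glycolysis and hypoxia, polyamines, the proteasome and p53 targets. Others covered growth and identity: S phase, mitosis, replication-dependent histones, Wnt signalling, immediate early genes, interferon response, and markers of erythroid, megakaryocytic, myeloid and lymphoid cells. The last were genes next to DDX3X, small nucleolar RNA hosts (SNHG), nuclear RNAs and structured small RNAs. A list of epithelial and fibroblast markers had fewer than 5 tested members and was not tested as a list. Lists were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. In the guide comparisons at days 3 and 14, 75 of 77 list calls of the preset test were lost with an estimated correlation. The number of members that passed is therefore given for most lists described, both over all genes and adjusted over the list alone. Not every called list is described: at day 14 the preset test called 16 lists in footprints and 12 in translational efficiency.

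The fits were tested on simulated counts drawn from the means and library sizes of these libraries with known changes. Changes were given to 199 genes in RNA, 198 in footprints and 196 in translational efficiency. These are fewer than the genes called at day 3 in the data, so the shares below need not carry over. Each recovered share rests on 65 to 67 genes. For RNA at day 3 (17843 genes), edgeR recovered 70.1% of genes changed 1.5-fold, 66.7% of those changed 2-fold and 97.0% of those changed 4-fold. For footprints at day 3 (19342 genes) the shares were 30.3%, 54.5% and 83.3%, and for translational efficiency at day 3 (14569 genes) they were 24.6%, 54.5% and 87.7%. In that draw 11.4% of the RNA calls, 11.2% of the footprint calls and 7.63% of the translational efficiency calls were false, against a nominal 5%. Over 6 draws the mean was 7.86% for RNA and 7.87% for footprints when each gene kept its own dispersion, and 4.98% and 3.92% when dispersions followed the trend. DESeq2 gave 4.80%, 6.31% and 4.55% in the first draw. The counts of genes given for edgeR can therefore hold more false calls than the nominal share.

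The alternatives were DESeq2 size factors in edgeR, no filter on low counts, the replicate number as a block, the RNA and footprint library of the same guide, day and number as a block, the DESeq2 Wald test, limma-voom with weights per assay, and leaving out each library in turn. Protein-coding genes alone and the newer quasi-likelihood fit of edgeR were added after the data had been seen. Where a library is left out, the remaining one of its group is assumed to vary like the other groups.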

Results

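Ribosome footprints and cytosolic RNA were sequenced in K562 cells in which CRISPR interference was aimed at DDX3X, and in cells with the control guide sgGal4. Cells were taken at day 0, day 3 and day 14, with 2 libraries for each guide, day and assay, 12 libraries per assay. RNA-seq libraries held 1.03e+07 to 4.33e+07 counts and footprint libraries 6.22e+06 to 1.52e+07. Protein-coding genes took 76.1% to 77.7% of the RNA-seq counts and 60.8% to 66.9% of the footprint counts. Among footprints, 9.41% to 14.1% of counts lay in U1 to U6 small nuclear RNA genes and 4.50% to 6.20% in mitochondrial ribosomal RNA. Among RNA-seq counts, 7.43% to 9.24% lay in 7SL and 7SK RNA. The comparisons ask what loss of the helicase does to the abundance of mRNAs and to their translation, early (day 3) and later (day 14) in the knockdown, and what the control cells do over the same days.

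DDX3X, which encodes an RNA helicase and lies on chromosome X at 41333308 to 41364472 of GRCh38, was reduced at both later days in the sgDDX3 cells. At day 0 its RNA was at 179 ± 8.80 CPM with sgDDX3 and 206 ± 9.12 CPM with sgGal4 (SD, n = 2 each), 86.9% of the control. At day 3 it was at 36.3 ± 4.21 against 182 ± 8.84 CPM (SD, n = 2 each), 5.01-fold lower. At day 14 it was at 118 ± 23.6 against 195 ± 9.28 CPM (SD, n = 2 each), 1.65-fold lower. Footprints on DDX3X were at 139 ± 12.01 against 153 ± 1.33 CPM at day 0, 33.3 ± 7.58 against 144 ± 3.37 CPM at day 3 (4.32-fold lower) and 105 ± 8.47 against 162 ± 9.28 CPM at day 14 (1.55-fold lower; SD, n = 2 each). In the edgeR fits the log2 difference in RNA was -0.21 ± 0.10 (SE; adjusted p = 0.999) at day 0, -2.29 ± 0.11 (adjusted p = 1.6e-11) at day 3 and -0.72 ± 0.10 (adjusted p = 4.0e-05) at day 14. In footprints it was -2.04 ± 0.12 (adjusted p = 2.4e-06) at day 3 and -0.61 ± 0.11 (adjusted p = 0.00928) at day 14. The translational efficiency of DDX3X itself did not pass at day 3 (0.25; adjusted p = 0.452) or day 14 (0.11; adjusted p = 0.856). Between day 3 and day 14 the difference narrowed by 1.57 in RNA and 1.43 in footprints on the log2 scale, and both passed the test between days. The day 14 footprint call was lost without sgDDX3 replicate 1 (-0.67) or sgDDX3 replicate 2 (-0.56).

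Of 6 genes next to DDX3X tested in RNA at day 3, 2 rose and 0 fell (2 and 0 adjusted over the list alone). They were USP9X, a deubiquitinase gene at 41085445 to 41236579 (0.37 ± 0.08), and CASK, a scaffold protein gene at 41514934 to 41923554 (0.42 ± 0.14). The USP9X call was lost without sgGal4 replicate 2 (0.31). The CASK call was lost without sgDDX3 replicate 1 (0.39), sgDDX3 replicate 2 (0.45), sgGal4 replicate 1 (0.34) or sgGal4 replicate 2 (0.48), and also by DESeq2 (adjusted p = 0.0985) and without the low-count filter (adjusted p = 0.0734). At day 14 CASK was higher by 0.75 ± 0.15 in every fit. USP9X was higher by 0.26 ± 0.08 at day 14, a call lost without sgDDX3 replicate 2 (0.16), sgGal4 replicate 1 (0.23) or sgGal4 replicate 2 (0.30), and also without the low-count filter (adjusted p = 0.0695).

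**Figure D1:**
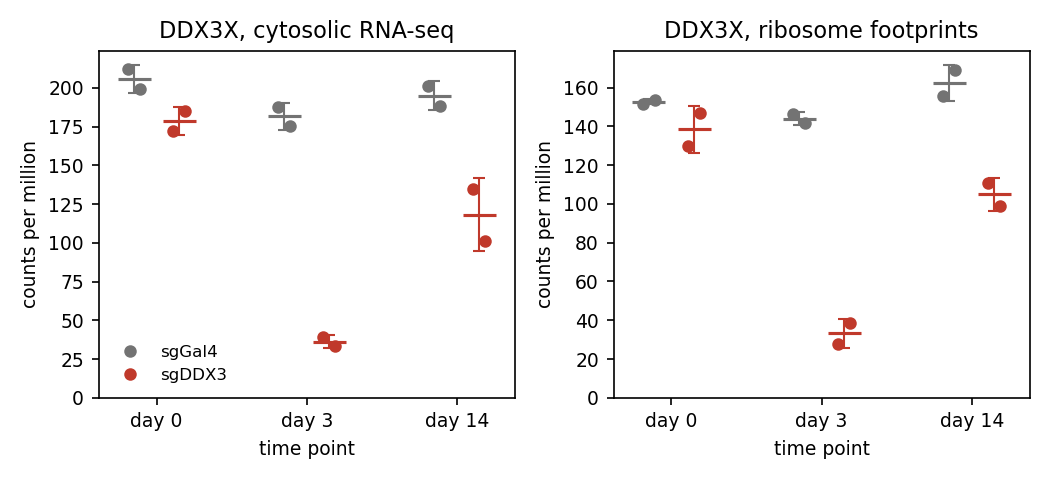
CPM of DDX3X in each library, RNA-seq and footprints, for sgDDX3 and sgGal4 at days 0, 3 and 14; points are libraries and bars the mean ± SD (n = 2). At day 3 the RNA means are 36.3 and 182 CPM, and at day 14 they are 118 and 195 CPM.

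At day 0 few genes passed with the low-count filter. Without it 33 passed in RNA, 282 in footprints (46.5% higher) and 22 in translational efficiency, and DESeq2 called 16 in footprints. With it, in RNA, the pseudogene PTPRVP alone passed and was higher with sgDDX3 (40.9 ± 3.58 against 24.9 ± 1.01 CPM, SD, n = 2; log2 difference 0.72, adjusted p = 0.00641 by edgeR). In footprints SNHG1, a host of small nucleolar RNAs, was higher by 0.81 ± 0.09 (SE; adjusted p = 0.00582). GOLGA8A, one of a gene family with near-identical copies, was higher by 0.80 ± 0.11 (adjusted p = 0.0494). SNHG1 also had a higher translational efficiency (0.77 ± 0.10, adjusted p = 0.00151). At an unadjusted p of 0.05, 4.55% of genes passed in RNA, 4.85% in footprints and 2.63% in translational efficiency. The PTPRVP call was lost without sgDDX3 replicate 1 (0.62), sgGal4 replicate 1 (0.67) or sgGal4 replicate 2 (0.76). In footprints the SNHG1 call was lost without sgDDX3 replicate 1 (0.79), sgDDX3 replicate 2 (0.82), sgGal4 replicate 1 (0.78) or sgGal4 replicate 2 (0.84), and the GOLGA8A call without sgDDX3 replicate 1 (0.70), sgDDX3 replicate 2 (0.90), sgGal4 replicate 1 (0.86) or sgGal4 replicate 2 (0.75), with the replicate block and in the newer fit. The efficiency call of SNHG1 was lost without sgGal4 footprint replicate 1 (0.73), and 3 genes passed without sgDDX3 footprint replicate 2. No list had a member that passed in RNA, and the 9 lists camera called with its preset correlation did not pass with an estimated one.

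At day 3, the RNA of ZNF628, a zinc finger protein, rose with sgDDX3, by a fitted 3.09-fold (64.2 ± 0.928 against 20.4 ± 1.90 CPM, SD, n = 2). The kinases MAP4K4 (433 ± 7.39 against 190 ± 6.26 CPM) and IRAK1 (266 ± 31.4 against 124 ± 3.01 CPM) at least doubled. Also higher were RCOR2 (log2 difference 1.51 ± 0.14, SE), AMIGO1 (1.38 ± 0.12), CCDC112 (1.25 ± 0.12), MYO15B (1.17 ± 0.11), IL18R1 (1.06 ± 0.15) and CYTH3 (0.99 ± 0.09). TMSB4X, the actin-binding thymosin, was at 98.5 ± 8.37 against 244 ± 11.8 CPM (-1.30 ± 0.09), and its pseudogene TMSB4XP8 (-1.27) can share its reads, so both values are uncertain. The Fc receptor FCGR2A, whose family has near-identical copies, was lower than with sgGal4 (-1.24 ± 0.14), as were transferrin (TF, -1.01 ± 0.17) and the erythroid gene HEMGN (-1.01 ± 0.12). TF rose from day 0 to day 3 in the sgGal4 cells, as given below. The non-coding RNAs PCAT14 (-1.002) and H19 (-0.93 ± 0.07, 99.4 against 189 CPM), and EFHD1 (-0.90 ± 0.15) and BCAS3 (-0.89 ± 0.13), were lower too. In all, 1405 genes were higher and 1169 lower of 18287 by edgeR, and DESeq2 called 2187. Without sgGal4 replicate 1 the count was 1389 and without sgGal4 replicate 2 it was 1338.

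Many genes of 3 cell cycle lists were lower at day 3. Camera called all 3 lists with its preset correlation and none with an estimated one (adjusted p = 0.0997 for histones, 0.0997 for mitosis and 0.149 for S phase). Of 36 replication-dependent histone genes, which supply chromatin in S phase, 32 fell and 0 rose (median log2 difference -0.53, from -0.63 to -0.42 over the alternatives; 35 adjusted over the list alone). They include H2BC11 (-0.84 ± 0.07) and H1-2 (-0.78 ± 0.07), though histone copies can share reads. Of 30 mitosis genes 23 fell (median -0.35; 26 adjusted over the list alone), among them the kinase AURKB (-0.68 ± 0.09), MAD2L1 (-0.48 ± 0.09) and TOP2A (-0.43 ± 0.08). Of 35 S phase genes 21 fell (median -0.33, from -0.43 to -0.24 over the alternatives; 30 adjusted over the list alone). Examples are RRM2, a subunit of ribonucleotide reductase (59.2 ± 6.44 against 102 ± 2.64 CPM, SD, n = 2), the licensing factor CDT1 (-0.65 ± 0.07), TK1 (-0.67 ± 0.10) and PCNA (-0.53 ± 0.08).

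Some members of lists for protein synthesis and breakdown fell at day 3, and no such list passed with an estimated correlation. The proteasome fell in 16 of 31 subunits (median -0.25, from -0.31 to -0.20 over the alternatives; 19 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation), for example PSMD4 (-0.39 ± 0.07) and PSMB3 (-0.44 ± 0.08). Of 27 integrated stress response genes 11 were lower than with sgGal4 (14 adjusted over the list alone, and adjusted p = 0.594 with an estimated correlation). They include SHMT2 (-0.47 ± 0.08) and the cystine transporter SLC7A11 (-0.66 ± 0.12). Many genes of this list rose from day 0 to day 3 in the sgGal4 cells, as given below. Of 20 tRNA synthetases 9 fell (14 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation), such as MARS1 (-0.43 ± 0.06). Of 76 mitochondrial ribosomal proteins 17 fell (22 adjusted over the list alone; adjusted p = 0.277 with an estimated correlation), such as MRPS18B (-0.42 ± 0.08). Of the large and small subunit ribosomal proteins, 0 of 47 and 2 of 32 rose by edgeR (0 and 2 adjusted over the list alone) and none fell.

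Erythroid genes moved both ways at day 3. Of 29 tested, 9 fell and 2 rose (12 and 3 adjusted over the list alone; adjusted p = 0.174 with an estimated correlation). The first enzyme of heme synthesis ALAS2 (79.2 ± 3.90 against 127 ± 6.73 CPM, SD, n = 2), UROD (-0.57 ± 0.08, SE) and the membrane protein RHAG (-0.74 ± 0.09) fell, and the cytoskeletal protein EPB41 rose (0.43 ± 0.06). In the cholesterol list 11 of 24 fell, with FDFT1 (-0.43 ± 0.06) and IDI1 (-0.47 ± 0.09), and 1 rose. The counts adjusted over that list alone were 12 and 3, with adjusted p = 0.282 with an estimated correlation. The preset call of the cholesterol list was lost without sgGal4 replicate 2 (adjusted p = 0.0543). Of 18 Wnt genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0997 with an estimated correlation). DVL3 (0.59 ± 0.07), CSNK1E (0.59 ± 0.07) and AXIN1 (0.67 ± 0.10) rose and MYC (-0.37 ± 0.07) fell. CD33, the 1 of 10 myeloid markers to pass, fell (-0.41 ± 0.08), as did CD7 (-0.32 ± 0.09), the 1 of 6 lymphoid markers. The CD7 call was lost without sgDDX3 replicate 1 (-0.36), sgDDX3 replicate 2 (-0.28) or sgGal4 replicate 1 (-0.25).

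At day 14 the RNA of the transcriptional regulator LMO4 was at 220 ± 20.3 against 67.6 ± 0.728 CPM (SD, n = 2), a log2 difference of 1.70 ± 0.08 (SE). The cytoskeletal protein ADD2 (1.96 ± 0.17), RCOR2 (1.63 ± 0.15) and ZNF628 (1.54 ± 0.10) were also raised. So were TSPOAP1 (1.52 ± 0.18), SNHG12 (1.39 ± 0.15), ZDHHC14 (1.29 ± 0.15), NPTXR (1.20 ± 0.14) and CDR2L (1.20 ± 0.15). H19 was at 94.3 ± 1.52 against 285 ± 10.0 CPM, and AKNA (-1.61 ± 0.24), FCGR2A (-1.53 ± 0.15) and the urea cycle enzyme ASS1 (-1.30 ± 0.20) were lower. UNC5B (-1.30 ± 0.17), TF (-1.18 ± 0.18), IGFBP2 (-1.14 ± 0.11) and the mucin MUC4 (-1.06 ± 0.15) were lower too. The mitochondrial ribosomal RNAs MT-RNR1 (-1.21 ± 0.24) and MT-RNR2 (-1.20 ± 0.26) were lower by edgeR and did not pass in DESeq2. Ribosomal RNA had been depleted from these libraries. Together they held 0.0203% and 0.0205% of counts with sgDDX3 at day 14 and 0.0422% and 0.0515% with sgGal4. At days 0 and 3 the range over both guides was 0.0058% to 0.0166%, so the sgDDX3 values at day 14 did not lie below it. The MT-RNR2 call was lost without sgGal4 replicate 2 (-1.05). In all, 1543 genes were higher and 1131 lower by edgeR, and DESeq2 called 2184. Without sgGal4 replicate 1 there were 1536 genes and without sgGal4 replicate 2 there were 1076. Without the low-count filter 48.1% of 2659 calls were higher, against 57.7% with it, so the balance turned.

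The integrated stress response list, made up of targets of ATF4 and related factors, had 21 of 27 genes lower at day 14 (median -0.62; 26 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation). The median was -0.37 without sgDDX3 replicate 1 and -0.91 without sgDDX3 replicate 2. Examples were TRIB3 (162 ± 43.2 against 320 ± 9.83 CPM, SD, n = 2), PCK2 (-0.75 ± 0.09, SE), SHMT2 (-0.67 ± 0.08) and SLC3A2 (-0.48 ± 0.07), and ATF4 itself fell (-0.41 ± 0.07). Of 20 tRNA synthetases 11 fell (13 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation), with MARS1 (-0.63 ± 0.06) and WARS1 (-0.71 ± 0.11). Ribosomal protein mRNAs were lower by small amounts, for example RPL24 (-0.30 ± 0.06) and RPSA (-0.30 ± 0.06), as was the elongation factor EEF2 (-0.30 ± 0.06). These were 15 of 47 of the large subunit, 7 of 32 of the small subunit and 11 of 23 other TOP mRNAs. Adjusted over the list alone they were 22, 8 and 12, and adjusted p = 0.407, 0.407 and 0.311 with an estimated correlation.

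Histone genes were still lower at day 14, in 31 of 36 (34 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation), with H2BC11 (-0.73 ± 0.07) and H3C10 (-0.75 ± 0.08). Of 30 mitosis genes 7 fell and 0 rose (11 and 3 adjusted over the list alone). Of 35 S phase genes 3 fell and 3 rose (6 and 3 adjusted over the list alone), with CDT1 lower (-0.62 ± 0.07) and the helicase subunit MCM2 higher (0.70 ± 0.12). Of 21 immediate early genes 9 fell (9 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation), with EGR1 (-0.90 ± 0.09) and MYC (-0.62 ± 0.07). Of 19 interferon response genes 7 rose (7 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation), among them OAS3, an activator of RNase L (9.29 ± 0.412 against 0.892 ± 0.0989 CPM, SD, n = 2). Mitochondrial ribosomal proteins fell in 20 of 76 (30 adjusted over the list alone) and proteasome subunits in 9 of 31 (16 adjusted over the list alone). Erythroid genes fell in 8 and rose in 4 of 29 (9 and 5 adjusted over the list alone), with ALAS2 lower (-0.63 ± 0.07). SNHG transcripts rose in 5 and fell in 1 of 14 (5 and 2 adjusted over the list alone).

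**Figure D2:**
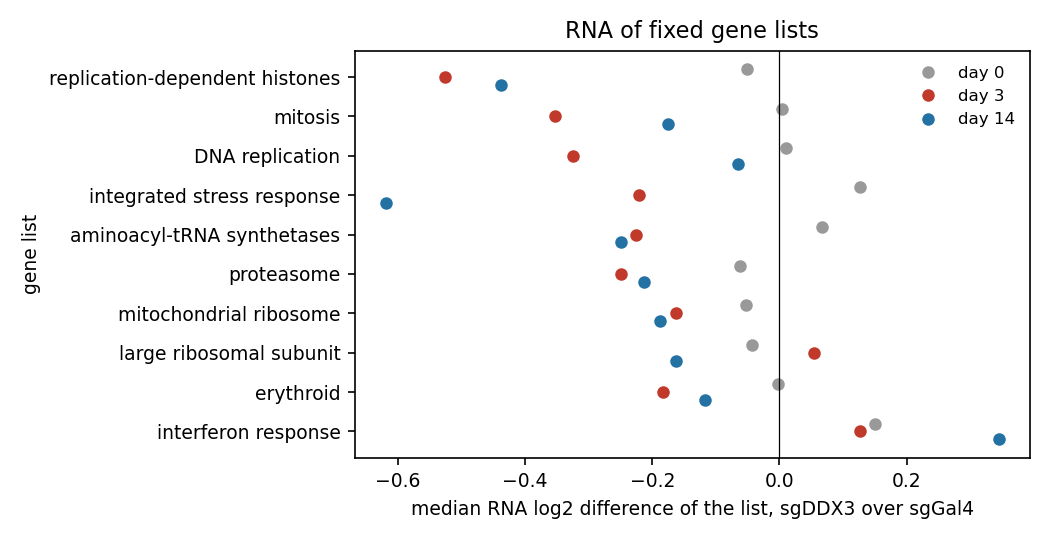
Median RNA log2 difference, sgDDX3 over sgGal4, of 10 fixed gene lists at days 0, 3 and 14; each point is the median over the tested members of a list, with no error drawn. At day 14 the integrated stress response median is -0.62 (-0.91 to -0.37 over the alternatives) and at day 3 the histone median is -0.53 (-0.63 to -0.42).

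Other groups had changed RNAs in few members or in both directions at day 14, by edgeR, given here as genes that rose and fell. Initiation factors counted 7 and 9 of 36 (8 and 12 adjusted over the list alone), with the subunit joining factor EIF5B higher (0.98 ± 0.10), the scaffold EIF4G1 higher (0.83 ± 0.12) and EIF4EBP1, which binds eIF4E, lower (-0.69 ± 0.08). RNA helicases counted 7 and 0 of 39 (7 and 0 adjusted over the list alone), with DHX9 (0.35 ± 0.07) among them. mRNA export factors counted 2 and 1 of 28 (2 and 1 over the list alone), and stress granule proteins 3 and 1 of 23 (3 and 1). ER chaperones counted 7 and 1 of 21 (11 and 3 over the list alone), with XBP1, a factor of the unfolded protein response, at -0.62 ± 0.08. Heat shock genes counted 4 and 2 of 17 (4 and 2), and ribosome biogenesis genes 3 and 0 of 31 (3 and 0), with nucleolin NCL higher (0.44 ± 0.09). Nuclear genes of oxidative phosphorylation counted 0 and 6 of 76 (0 and 6), and mitochondrially encoded genes 5 and 0 of 13 (5 and 0), with MT-ND2 higher (0.73 ± 0.12). The MT-ND3 call was lost without sgDDX3 replicate 2 (0.19) or sgGal4 replicate 1 (0.25), and by DESeq2 (adjusted p = 0.0691). That of MT-ATP8 was lost without sgGal4 replicate 1 (0.59). Mitochondrial mRNA held 5.37% and 7.16% of counts with sgDDX3 and 5.95% and 6.62% with sgGal4. The p53 targets counted 3 and 5 of 17 (3 and 6), and glycolysis and hypoxia genes 1 and 3 of 27 (1 and 3). Megakaryocytic markers counted 1 and 1 of 10 (1 and 2), and myeloid markers 0 and 2 of 10 (0 and 2), with CD33 lower (-0.62 ± 0.09). Nuclear RNAs counted 1 and 0 of 8 (1 and 0), with MALAT1 higher (0.49 ± 0.07), and structured small RNAs 1 and 0 of 6 (3 and 0).

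Footprints at day 3 fell most clearly on a few mRNAs. Those on ODC1, the first enzyme of polyamine synthesis, were at 61.2 ± 6.49 against 206 ± 7.01 CPM (SD, n = 2; log2 difference -1.75 ± 0.11, SE; adjusted p = 2.4e-06). Those on NT5DC2 (24.8 ± 0.466 against 72.6 ± 0.0174 CPM), on the endocytic adaptor EPN1 (-1.52 ± 0.13) and on EIF4EBP2, which binds the cap-binding protein (-1.33 ± 0.11), were lower too. The nucleotide synthesis genes TYMS (-0.71 ± 0.08) and RRM2 (-0.70 ± 0.09), CDT1 (-0.72 ± 0.10), ALAS2 (-0.67 ± 0.09) and EGR1 (-0.98 ± 0.14) were lower as well. The receptor subunit GRIK3 (2.28 ± 0.25) and SNHG1 (0.60 ± 0.09) were higher, and LINC02955 was lower (-5.22 ± 0.50). Footprints on SNHG1 were already called higher at day 0, as given above. The LINC02955 difference went with a gain in the sgGal4 cells, from 1.88 CPM at day 0 to 40.4 CPM at day 3. With sgDDX3 its values were 0.836 and 1.01 CPM. LRFN2 (2.74 ± 0.66) and TMTC2 (1.81 ± 0.25) were also called higher. The LRFN2 call was lost without sgDDX3 replicate 2 (1.21), sgGal4 replicate 1 (3.19) or sgGal4 replicate 2 (2.46), and the TMTC2 call without sgGal4 replicate 1 (1.56). In all, 306 genes were higher and 446 lower by edgeR of 19780, and DESeq2 called 581. The count was 401 without sgDDX3 replicate 2, 119 without sgGal4 replicate 1 and 135 without sgGal4 replicate 2. The share of these that were higher was 66.3%, 14.3% and 20.0%, against 40.7% with all libraries, so the balance of higher and lower turned without sgDDX3 replicate 2. Among lists, 7 of 35 S phase genes, 8 of 41 histone genes and 5 of 10 earlier DDX3X targets fell (13, 19 and 7 adjusted over the list alone; adjusted p = 0.495, 0.564 and 0.0755 with an estimated correlation).

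Footprints at day 14 were higher on the interferon gene IFI6 (11.4 ± 0.831 against 3.32 ± 0.714 CPM, SD, n = 2) and the initiation factor EIF5B (142 ± 13.9 against 38.3 ± 6.10 CPM). Also higher were EIF4G1 (1.16 ± 0.16, SE), the helicase DHX9 (1.38 ± 0.20) and MCM2 (1.69 ± 0.23). They were lower on ODC1 (99.6 ± 9.40 against 202 ± 8.06 CPM), the transcription factor SOX5 (-1.34 ± 0.16), the GTPase RAB6B (-1.12 ± 0.16) and H19 (-1.71 ± 0.27). They were also lower on TMSB4XP2 (-1.11 ± 0.09) and TMSB4XP4 (-1.05 ± 0.15), pseudogenes that can share reads with TMSB4X. The highest values lay on microRNA and small RNA genes: MIR191 (4.34 ± 0.46), MIR16-2 (4.21 ± 0.58), SNORA74D (3.47 ± 0.51), MIR93 (2.98 ± 0.42), MIR320A (2.47 ± 0.30) and MIR17HG (995 ± 423 against 174 ± 13.4 CPM). U2 copies were higher too, for example RNU2-17P (2.93 ± 0.32), and copies of this family can share reads. Of 27 integrated stress response genes 10 fell (22 adjusted over the list alone; adjusted p = 0.300 with an estimated correlation). Of 19 interferon genes 5 rose (6 adjusted over the list alone; adjusted p = 0.0814 with an estimated correlation). In all, 417 genes were higher and 255 lower by edgeR, and DESeq2 called 550. The count was 144 without sgDDX3 replicate 1, 378 without sgDDX3 replicate 2 and 213 without sgGal4 replicate 1. With protein-coding genes only, in the scaling and the tests, 47.5% of 883 calls were higher, against 62.1% with all genes, so the balance turned. In the fit of all genes the protein-coding calls were 294 higher and 222 lower.

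Among genes that passed, translational efficiency at day 3 was lower far more often than higher. Each assay was scaled within itself, so efficiency is relative to the other genes and a change common to all mRNAs cannot be seen. The median log2 difference over all 14853 genes was 0.0515. The ratio of mean footprint CPM to mean RNA CPM (n = 2 each) was 0.131 against 0.543 for NT5DC2 (log2 difference -2.05 ± 0.14, SE; adjusted p = 5.6e-10), 0.111 against 0.427 for the kinase MAP4K4 (-1.94 ± 0.13) and 0.0471 against 0.162 for EIF4EBP2 (-1.79 ± 0.13). ZNF628 (-1.99 ± 0.19), AGBL5 (-1.93 ± 0.17), EPN1 (-1.75 ± 0.15), the syntaxin STX3 (-1.74 ± 0.12), the ceramide kinase CERK (-1.70 ± 0.19) and TOPBP1, which acts at stalled replication forks (-1.69 ± 0.16), were also lower. Higher were FCGR2A (1.78 ± 0.30), uncertain because of its near-identical copies, ANXA2R (1.23 ± 0.21) and SMAD6, an inhibitor of BMP signalling (1.10 ± 0.22). The demethylase FTO (1.79 ± 0.44) passed too, and that call was lost without sgDDX3 footprint replicate 2 (0.58), sgGal4 footprint replicate 1 (1.88), sgGal4 footprint replicate 2 (1.69), sgDDX3 RNA replicate 1 (1.80) or sgGal4 RNA replicate 1 (1.78), and also by limma-voom (1.54, adjusted p = 0.0555). In all, 659 genes were lower and 104 higher by edgeR of 14853, and DESeq2 called 751. The count was 505 without sgDDX3 footprint replicate 2 and 465 without sgGal4 footprint replicate 1.

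Of the 659 genes with lower efficiency at day 3, among them MAP4K4 and ZNF628, 436 were also called higher in RNA. Footprints were called lower for 235, as for ODC1 and NT5DC2, and 88 passed in neither. The median log2 difference of the 659 was 0.37 in RNA and -0.42 in footprints. Of the 104 genes with higher efficiency, 33 were called lower in RNA, FCGR2A among them, and 32 higher in footprints. The same RNA libraries enter the RNA difference and the efficiency, and the overlap of 436, against 61.1 for independent lists, holds an unknown part that comes from sharing them. In simulated unchanged groups (mean of 5 draws) 0 genes were called lower in efficiency and 1 higher in RNA, so the simulation gives no overlap to compare. Across genes the correlation of the 2 values was -0.51 against -0.56 in the simulation, and their covariance -0.0727 against -0.0355.

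**Figure D3:**
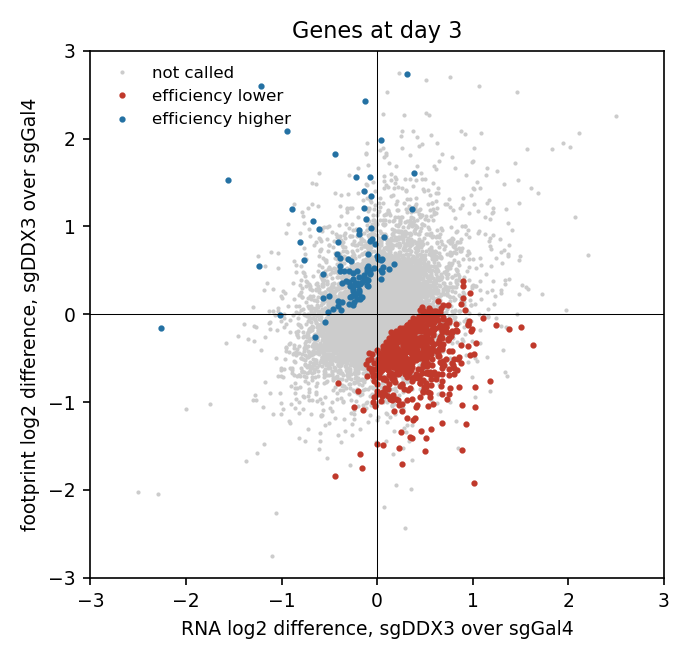
Log2 difference, sgDDX3 over sgGal4, in RNA (horizontal axis) and in footprints (vertical axis) at day 3, one point per gene tested in both assays (14853; 4 lie outside the axes). The 659 genes lower in translational efficiency and the 104 higher ones are coloured.

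Messages that earlier work named as dependent on DDX3X had lower efficiency as a group at both days. At day 3, 7 of 10 fell and 0 rose (median -0.65; 8 adjusted over the list alone; adjusted p = 5.7e-05 with an estimated correlation). The RNA of this list at day 3 was higher in 4 and lower in 1 (median 0.18; 4 and 1 adjusted over the list alone; adjusted p = 0.0997 with an estimated correlation), and the same RNA libraries enter the efficiency. The ratio of ODC1, on chromosome 2 at 10439968 to 10448327, was 0.237 against 0.717, a log2 difference of -1.60 ± 0.13 (SE; adjusted p = 9.1e-09). The Wnt mediators DVL2 (-1.21 ± 0.17) and DVL1 (-1.06 ± 0.16) and PRKRA, an activator of the kinase PKR (-0.83 ± 0.13), were lower. The GTPase RAC1 (-0.39) also passed, while CCNE1 (-0.51, adjusted p = 0.0735), ATF4 (0.13) and MITF (-0.02) did not; these 4 members lie outside the rule for named genes and were not refitted with the alternatives. At day 14 the median was -0.28 (-0.33 to -0.21 over the alternatives) and 2 of 10 fell (3 adjusted over the list alone; adjusted p = 0.00391 with an estimated correlation), ODC1 (-0.96 ± 0.13) and PRKRA (-0.56 ± 0.13). The day 14 call of PRKRA was lost without sgDDX3 footprint replicate 1 (-0.52), sgGal4 footprint replicate 2 (-0.49), sgDDX3 RNA replicate 2 (-0.49) or sgGal4 RNA replicate 2 (-0.48), and also without the low-count filter (adjusted p = 0.0892).

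Wnt signalling genes outside that list had lower efficiency at day 3 as well, 4 of 16 (5 adjusted over the list alone; adjusted p = 0.379 with an estimated correlation). They include the scaffold AXIN1 (-1.50 ± 0.19), the kinase CSNK1E (-0.82 ± 0.14) and DVL3 (-0.76 ± 0.12). The RNA of AXIN1, CSNK1E and DVL3 was higher at day 3, as given above, and the same RNA libraries enter the efficiency. Of 36 initiation factors, EIF4EBP2 and PAIP1, a partner of the poly(A)-binding protein (-0.60 ± 0.10), were the 2 that fell and 1 rose (2 and 1 adjusted over the list alone). In the polyamine list ODC1 and spermidine synthase SRM (-0.68 ± 0.14) fell and AZIN1, which protects ODC1 from breakdown (0.59 ± 0.10), rose, 3 of 12 (2 lower and 2 higher adjusted over the list alone). Single members of other lists that fell were the S phase regulator E2F1 (-1.17 ± 0.19), JUND (-1.06 ± 0.16) and CRELD2 (-1.34 ± 0.20). By edgeR 0 of 47 large and 0 of 32 small subunit ribosomal proteins fell in efficiency at day 3 (0 and 0 adjusted over the list alone). As a list, camera with its preset correlation called the large subunit, with a lower median (-0.16 to -0.077 over the alternatives). It also called lists with higher medians, among them histones (0.17 to 0.33), mitosis (0.094 to 0.31), the proteasome (0.064 to 0.20) and nuclear oxidative phosphorylation (0.053 to 0.19). None of these passed with an estimated correlation (adjusted p = 0.934 each).

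**Figure D4:**
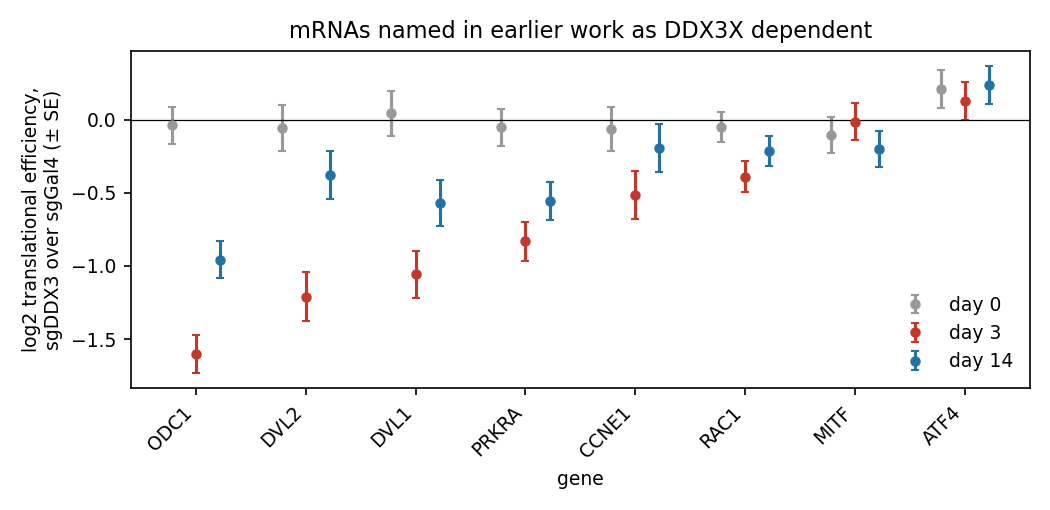
Log2 difference in translational efficiency, sgDDX3 over sgGal4, of 8 of the 10 mRNAs named in earlier work, at days 0, 3 and 14; bars are ± SE from the joint edgeR model. ODC1 is at -1.60 at day 3 and -0.96 at day 14.

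At day 14, ZNF628 (-1.65 ± 0.18, SE), MAP4K4 (ratio 0.168 against 0.442; -1.40 ± 0.12), CERK (-1.33 ± 0.18) and NT5DC2 (-1.08 ± 0.13) still had lower efficiency. Others lower were KIAA1958 (-1.18 ± 0.18), ZMYND19 (-1.11 ± 0.17), MICALL1 (-1.06 ± 0.16) and PRKACA, the catalytic subunit of protein kinase A (-1.06 ± 0.13). PANK3, which starts coenzyme A synthesis (-1.05 ± 0.15), GALNT10 (-1.03 ± 0.13) and EIF4EBP2 (-0.84 ± 0.12) were lower as well. Higher were FCGR2A (1.79 ± 0.31), the transcription elongation factor SUPT6H (1.19 ± 0.17) and PDCD11, a ribosome biogenesis protein (1.09 ± 0.18). The non-coding microRNA host MIR17HG (2.65 ± 0.43) also passed as higher, which need not be translation. DHX9 (1.03 ± 0.21) passed too and was lost without sgDDX3 footprint replicate 1 (0.88) or sgGal4 footprint replicate 1 (0.90). In all, 204 genes were lower and 56 higher by edgeR, and DESeq2 called 276. Protein-coding genes made up 197 of the 204 lower and 29 of the 56 higher. The count was 134 without sgDDX3 footprint replicate 1, 144 without sgGal4 footprint replicate 1, 135 without sgGal4 RNA replicate 1 and 100 without sgGal4 RNA replicate 2. Genes lower at both days, such as ODC1, numbered 182, against 9.05 for independent lists. The days share no libraries, but they share 1 fit and its spread per gene.

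The change of the guide difference between days was tested directly. From day 3 to day 14 the RNA difference changed in 15 genes upward and 15 downward. The guide difference of LMO4 moved up by 0.81 and that of SNHG12 by 1.16 on the log2 scale, and that of H19 moved down by 0.67. A change in the cells of either guide can move this difference, and for H19 it went with a rise in the sgGal4 cells. In footprints 25 genes changed upward over the same days, NT5DC2 by 0.90, and 0 downward, a balance that was not stable. The share upward was 57.8% of 135 genes without sgDDX3 day 3 replicate 2, 64.7% of 17 without sgGal4 day 14 replicate 1 and 58.2% of 471 without the low-count filter, and 2 genes passed with protein-coding genes only. For efficiency edgeR called 0 genes between day 3 and day 14, where 751 had an unadjusted p under 0.05 and DESeq2 called 15. Against day 0, the RNA difference had changed by day 3 in 434 genes upward and 242 downward, and by day 14 in 487 upward and 329 downward (59.7% upward, and 48.8% without the low-count filter). For efficiency 256 genes went down and 12 up by day 3, and 18 down and 4 up by day 14 (18.2% up, and 57.1% of 7 without sgDDX3 day 0 RNA replicate 1). Integrated stress response genes rose over time in the control cells, 18 of 27 by day 3 (median 0.37) and 20 of 27 by day 14 (median 0.39). Their guide difference at day 14 against day 0 was lower in 19 of 27 (median -0.73). These list values over time were not refitted with the alternatives. At day 14 itself the median guide difference of the list ranged from -0.91 to -0.37 over the alternatives. Of the RNA calls at day 3, 1414 were also called at day 14, 1408 of them in the same direction, against 190.8 for independent lists. These counts moved with single libraries: RNA from day 0 to day 3 gave 255 without sgGal4 day 0 replicate 1, to day 14 gave 1588 without sgDDX3 day 14 replicate 2 and 335 without sgGal4 day 0 replicate 1, and from day 3 to day 14 gave 314 without sgDDX3 day 14 replicate 2 and 9 without sgGal4 day 3 replicate 1. Efficiency gave 2 from day 0 to day 14 without sgDDX3 day 0 RNA replicate 2, and 19 from day 3 to day 14 without sgDDX3 day 14 footprint replicate 2.

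In the control cells, RNA changed with time as well. TF rose by 1.94 ± 0.18 (SE) by day 3 and by 1.74 ± 0.19 by day 14. PRSS8 (1.43 ± 0.18), the proteoglycan SDC3 (1.19 ± 0.12) and SOCS1, an inhibitor of cytokine signalling (1.18 ± 0.10), rose by day 3. The adhesion ligand SELPLG (-1.03 ± 0.11 by day 3, -1.12 ± 0.11 by day 14), SIGLEC6 (-0.91 ± 0.13 by day 3) and the stem cell factor receptor KIT (-0.94 ± 0.10 by day 14) fell. In RNA 623 genes rose and 415 fell by day 3, and 1408 rose and 1563 fell by day 14, by edgeR. At day 14 47.4% rose, and the balance turned without the low-count filter (53.1%), with protein-coding genes only (51.1%), and without sgGal4 day 0 replicate 1 (52.0%) or day 14 replicate 1 (56.2%). In footprints 139 rose and 111 fell by day 3, and 304 rose and 184 fell by day 14. Leaving out single libraries gave as few as 96 genes in RNA at day 3 (sgGal4 day 3 replicate 1), 946 at day 14 (day 0 replicate 1), 10 in footprints at day 3 (day 0 replicate 1) and 44 at day 14 (day 0 replicate 2).

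Footprint counts in the control cells rose on TMTC2, on chromosome 12 at 82686906 to 83134866, from 1.29 ± 0.127 CPM at day 0 to 54.3 ± 11.8 at day 3 and 63.3 ± 29.8 at day 14 (SD, n = 2). On LINC02955, on chromosome 12 at 22699859 to 23191587, they rose from 1.88 ± 0.220 to 40.4 ± 8.89 and 53.1 ± 29.5 CPM (SD, n = 2). The rise by day 14 was 5.58 ± 0.39 for TMTC2 and 4.79 ± 0.38 for LINC02955 on the log2 scale (SE). With sgDDX3, TMTC2 was at 3.17 ± 1.18, 181 ± 4.58 and 80.2 ± 15.8 CPM, and LINC02955 at 0.836 ± 0.495, 1.01 ± 0.290 and 0.658 ± 0.272 CPM (SD, n = 2).

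**Figure D5:**
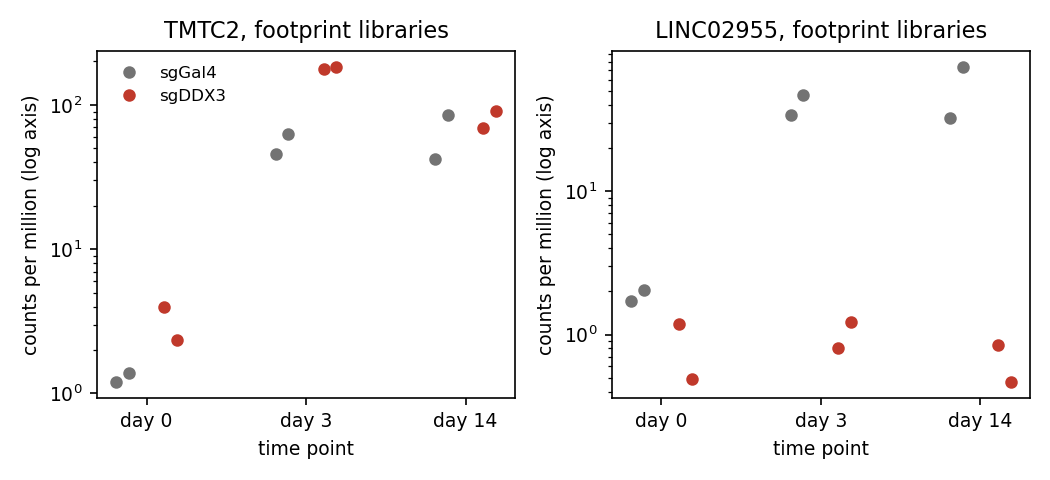
Footprint CPM, on a log axis, of TMTC2 and LINC02955 in each library for both guides at days 0, 3 and 14; points are libraries (n = 2). LINC02955 is at 40.4 CPM with sgGal4 and 1.01 CPM with sgDDX3 at day 3.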

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

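The tests of the change between days were planned before any value was seen, and of the tests of explanations those on dose of DDX3X and on outgrowth were written before the result was seen; the others, and the comparison of the dose test with the size of the DDX3X loss, were chosen only after. A difference between days in the guide effect, tested directly by edgeR, marked these results. In RNA it was passed by 676 genes for day 3 against day 0, 816 for day 14 against day 0 and 30 for day 14 against day 3. Named genes in RNA for day 14 against day 3 were SNHG12 (1.156), LMO4 (0.806), H19 (-0.669), PCAT14 (0.795) and DDX3X (1.572). In footprints it was passed by 24, 21 and 25 genes for the same 3 contrasts, and for translational efficiency by 268, 22 and 0. Named genes in footprints for day 14 against day 3 were NT5DC2 (0.896) and DDX3X (1.43). Small RNA genes there were MIR191 (5.499), MIR16-2 (6.077), MIR16-1 (5.492), MIR93 (4.854), MIR320A (3.508), MIR17HG (3.378), SNORA74D (4.698), RNU2-17P (3.501), RNU2-9P (3.212) and RNU2-32P (2.981).

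Genes lower in translational efficiency at day 3 had higher RNA and lower footprints by their medians, and 100 of 659 were called in both. Chance error in the day 3 RNA-seq libraries would leave no difference at day 14, where other libraries were used. The median RNA difference of these genes there was 0.27 (0.2706), which argues against chance error as the whole cause. More nuclear RNA in the sgDDX3 lysates would raise nuclear transcripts alike by about the 0.3676 of the pattern, and the median of 8 was -0.1626 (SD 0.1838) with 0 at or above it, or -0.1599 without NORAD, which is largely cytoplasmic; this argues against it as the whole cause. Within the list MALAT1 alone goes with it, higher by 0.32 ± 0.07 (SE), a call lost without sgGal4 replicate 2. The list held 1.026% and 0.981% of counts with sgDDX3 against 0.921% and 0.792% with sgGal4. Outside the list, U1 to U6 small nuclear RNA genes held 0.141% and 0.149% against 0.123% and 0.117%. A smaller part is therefore left open. Lower translation in proportion to the loss of DDX3X predicts a weaker effect at day 14. Over genes chosen at day 14 the day 3 median was lower by 0.2372 (-0.2372). Their medians at days 3 and 14, -0.9214 and -0.6842, stood at 1.347 to 1. Those of genes chosen at day 3, -0.7581 and -0.4423, stood at 1.714 to 1. Choosing genes at a day favours a larger value at that day. DDX3X RNA stood at 3.187 to 1 on the log2 scale, and was at 20.0% and 60.6% of sgGal4. The 0 efficiency changes that edgeR called between these days cannot decide, with a median SE of 0.278. A weaker effect is seen. Whether it is proportional stays open, since gene set and scale change the ratios and protein was not measured. Bias by GC content or by 5′ leader structure was not tested, and shared RNA libraries link the 2 measures by construction.

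RNA differences between the guides were as many at day 14 as at day 3 although DDX3X RNA had come back in part. Drift of the 2 lines unrelated to day 3 predicts no shared direction. Genes called in the same direction at both days were 7.378 times the number for independent lists. Both days share 1 fit and its spread per gene, which can raise this overlap by itself. Of the genes called at both days, 1408 had the same direction and 6 the opposite, which argues against unrelated drift for those genes. A difference between the lines that was present by day 3 is not excluded. Outgrowth of cells without knockdown predicts that day 3 differences shrink with DDX3X. The median ratio of day 14 to day 3 was 0.7766 over genes called at day 3. Over genes called at day 14 the median ratio of day 3 to day 14 was 0.7198. Choosing genes at a day favours a larger value at that day, so both ratios are biased low. They gave no sign that RNA differences shrank as far as that of DDX3X, whose day 14 to day 3 ratio was 0.3138. No spread of these ratios was computed, so outgrowth stays open. For the 1260 genes called at day 14 alone, drift and a late effect of DDX3X cannot be told apart, because each guide is 1 line.

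Footprint libraries gained reads after day 0 at TMTC2 with both guides and at LINC02955 with sgGal4 alone. Transcription of the genes predicts more RNA-seq reads, and the highest RNA-seq count of TMTC2 in any library was 2, which argues against it for TMTC2. RNA of LINC02955 with sgGal4 was at 0.861 ± 0.0638, 1.08 ± 0.192 and 0.944 ± 0.0273 CPM at days 0, 3 and 14 (SD, n = 2), without the rise of its footprints from 1.88 to 40.4 and 53.1 CPM. Reads of an induced construct or guide RNA that align to these genes would go with doxycycline and with the guide, and footprints on LINC02955 pooled over days 3 and 14 were 56.12 times higher with sgGal4 than with sgDDX3 (40.4 against 1.01 CPM at day 3 and 53.1 against 0.658 at day 14). Counts hold no read sequences, so this stays open, and transcription is the 1 biological explanation tested.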

How the results depend on the processing

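Protein-coding genes only and the newer quasi-likelihood fit were chosen only after the result was seen; the other alternatives were planned. DDX3X kept its direction and call between guides in every other fit of all libraries: the 1 change was its efficiency for day 14 against day 0, -0.0057 with DESeq2 size factors (0.0032 otherwise). Of called and tested values of named genes, 525 of 552 were the same by DESeq2, 549 of 558 with size factors, 534 without filter, 538 with the replicate block, 553 in the newer fit, 477 of 479 with protein-coding genes, 73 of 80 by limma-voom and 74 of 80 with the block by culture; without each library in turn 1777 of 2552 were. Of lists, 75 of 77 calls were lost with an estimated correlation. Without each library in turn, each called list was counted once per fit, so a list can be counted several times. Of these list values 314 were the same, 76 weakened and 2 reversed. Counts that moved by over 1.5 times follow, and the cause was not tested.

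Without the low-count filter: RNA day 0 33, RNA day 14 against day 3 119; footprints day 0 282, day 3 1594, day 14 1221, the changes between days (day 3 to 0, 14 to 0, 14 to 3) 643, 384 and 471, sgGal4 day 3 963 and day 14 1249; efficiency day 0 22, day 14 against day 0 72 and against day 3 65. With protein-coding genes only, in the scaling and the tests: RNA day 0 0, footprint changes 81, 44 and 2, sgGal4 day 14 779, efficiency day 0 0 and day 14 against day 3 2. With the replicate block: footprints day 0 1, day 14 against day 3 59, efficiency day 14 against day 3 2; by culture efficiency day 0 4, day 14 against day 0 42 and against day 3 14. By DESeq2: footprints day 0 16, changes 112, 77 and 81, efficiency day 14 against day 0 55 and against day 3 15. With size factors: footprints day 14 against day 3 39, efficiency 4; by limma-voom efficiency 1; in the newer fit footprints day 0 1 and efficiency 3. Replicate numbers are not known to pair libraries. Residuals of the same number correlated at -0.1301 to 0.06006 within RNA, -0.2574 to 0.2202 within footprints and -0.02304 to 0.08498 between assays. These values show little pairing and cannot exclude shared cultures.

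Leaving out 1 library, with the lone library assumed to vary like the other groups, gave these lowest and highest counts. RNA: day 0 0 to 1, day 3 1338 to 1981, day 14 1076 to 3220, changes 255 to 661, 335 to 1588 and 9 to 314, sgGal4 96 to 664 and 946 to 1330. Footprints: 0 to 0, 119 to 726, 144 to 528, changes 5 to 173, 0 to 66 and 16 to 135, sgGal4 10 to 81 and 44 to 294. Efficiency: 0 to 3, 465 to 1000, 100 to 297, changes 179 to 369, 2 to 29 and 0 to 19. DDX3X ranged from -0.7173 to -0.3179 for RNA day 14 against day 0, -0.6727 to -0.5566 for footprints at day 14, and in efficiency -0.0016 to 0.4144 at day 3, -0.0701 to 0.3345 at day 14, and for the changes -0.1024 to 0.3137, -0.1674 to 0.2338 and -0.3106 to 0.119. RNA helicases ranged from -0.0517 to 0.2061 in footprints and -0.0038 to 0.2716 in efficiency at day 3, lowest without sgDDX3 footprint replicate 2, and PRKRA from -0.112 to 0.0035 in efficiency at day 0, highest without sgDDX3 RNA replicate 1. Fewer libraries, and so less power, go with the lower counts; the cause of the higher ones was not tested. Footprints had a biological coefficient of variation of 9.99% against 6.13% in RNA-seq, and the median footprint library held 9.48e+06 counts against 1.45e+07; whether depth limits the calls was not tested.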

Other observations

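AGTR2 was chosen after its values were seen, as were the small RNA genes of the footprint libraries named here, and no test of a hypothesis was added for them. Footprint libraries of sgDDX3 cells held reads on AGTR2, an angiotensin receptor gene, at 2.96 ± 0.774 CPM at day 3 and 2.25 ± 0.775 CPM at day 14 (SD, n = 2). With sgGal4 the value was 0 at both days, and RNA-seq counts were 0 in all libraries. Footprints on MIR17HG, the host of a microRNA cluster, were at 428 ± 213 CPM with sgDDX3 against 264 ± 108 CPM with sgGal4 at day 0, 290 ± 94.3 against 554 ± 124 CPM at day 3 and 999 ± 448 against 176 ± 13.7 CPM at day 14 (SD, n = 2), so the direction differed between days. Its RNA lay between 27.6 and 41.0 CPM in all groups. The lncRNA LINC02955 lay between 0.605 and 1.08 CPM in RNA in all groups.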
